A study of Mus musculus with 23 samples.

How the data were processed

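Total RNA of the left lung was measured on a NanoString nCounter mouse myeloid panel, which counts colour-coded probes hybridised to transcripts without amplification. Per the labels' protocols, the mice received 14 instillations of organic dust extract or of saline (PBS), the lungs were lavaged before the left lobe was taken, and the tissue was kept in RNAlater before extraction. Fat-1 mice carry a desaturase gene from Caenorhabditis elegans that converts omega-6 into omega-3 fatty acids, and wild-type (WT) mice lack it. Each of the 23 lungs came from a separate mouse, since a mouse has a single left lung.

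The deposited values are a signal, namely probe counts that were multiplied by a scale factor for each lung, per the file headers and the values themselves. The genes behind the factor and the software that computed it are not given in the sources used here. The factor, read from the spacing of the values, ran from 0.682 to 4.21 between lungs. Above the floor, 100.0% of values were whole multiples of that step within a tolerance of 0.1 steps. Values of 20 marked a floor, because counts under 20 had been set to 20 without scaling. In lungs with a factor under 1, counts that scaled to less than 20 were at 20 as well. The lowest value above the floor was 20.46 in the lung with a factor of 0.682. The lowest value above the floor therefore differed between lungs and reached 84.26 in the lung with the highest factor. The 14 control-probe entries, 6 positive and 8 negative, were whole raw counts. Because counts under the floor were hidden, no count model was fitted.

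The table held 754 genes, 734 endogenous and 20 housekeeping. Counts recovered above the floor ran from 110453 to 812429 per lung, and 66 to 232 genes per lung were at the floor. Counting error alone gives an SD of 4.47 at 20 counts, which is 22.4%, and its share falls as counts rise. In all lungs 43 genes were at the floor, and 470 genes were above it in every lung. Of the genes' accessions, 741 matched the RefSeq gene table used here, and 733 symbols were identical to it, so the deposited symbols were kept. Coordinates were not used here, and no genome build is given in the sources used here.

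Lungs were assigned to 8 groups of genotype, sex and exposure by the extract code, which per the labels' protocols records the extraction date, genotype, sex, exposure and replicate. The title, the characteristics and the code gave the same group for 19 lungs and different groups for 4. For 3 of these the code said Fat-1 where the title and characteristics said WT, with the sex also differing in 1 of them. For the other, the title said WT female dust where the code and characteristics said WT male saline. The characteristics gave groups of 1 to 4 lungs, against 3 per group in the design text. Lungs had been extracted on a pair of days, called day 1 (12 lungs) and day 2 (11 lungs), and hybridised on a pair of cartridges that nearly followed the days, with 2 lungs of each day on the other day's cartridge. Lungs are named by group, replicate number and day. Between lungs of the same group, chi-square per degree of freedom of the recovered counts was 4.14 to 226, so that no pair looked like the same library deposited again.

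Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, and fold changes are on that scale. The added 1 lowers them only slightly, since no value is under 20. For low genes the floor, set before scaling, can make a change look smaller or larger than it was. A group-means model over all 23 lungs gave 8 contrasts with empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over the 711 genes with a mean of at least 20 that were above the floor in at least 1 lung. The floor keeps every mean at 20 or higher, so the second condition did the filtering. Of the tested genes, 241 were at the floor in 1 or more lungs. The threshold was an adjusted p under 0.05. Gene lists, 22 in number, were fixed before the data were examined, and the 18 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with the other genes of a panel that is itself a myeloid selection. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

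The groups, contrasts, tests, lists, naming rule and most alternatives were chosen before the data were examined. By the naming rule, dust against saline gave the 12 highest and 12 lowest genes past the threshold with the same sign in all 4 strata of sex and genotype. Other contrasts gave the 5 highest and 5 lowest, or the 3 with the smallest p where fewer than 3 passed, and each list gave up to 4 members with the smallest p. List members that moved against their list, genes of the lists under 5 members, and genes called under an alternative setting in counts of 15 or fewer were named after their values were seen. A gene that the rule takes is not reported here, and it was left out of the counts of single-gene values while staying in the tests and in the counts of its lists.

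Alternatives planned beforehand were leaving out the 4 lungs with differing labels, groups from the characteristics, day as a covariate, each day alone, the replicate number within day as a block, a pseudocount of 10, no filter or a mean of at least 50, median centring of each lung, a variance trend, a fit of only the groups compared, and leaving out each lung in turn. Chosen after seeing the data were the cartridge as a covariate, each cartridge alone, a common floor of 84.26 in every lung, genes above the floor in at least 12 lungs, scaling to the housekeeping genes, day by exposure as covariates, and leaving out 4 lungs in doubt on technical measures. These were Fat-1 male dust lung 1 of day 2 and WT male saline lung 1 of day 2, with binding densities of 3.05 and 3.12 against at most 1.32 elsewhere, WT female saline lung 1 of day 2, with a positive-control geometric mean of 1904 counts, and Fat-1 female dust lung 2 of day 1, with the lowest linearity of the positive controls (R² of 0.956).

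The fit was tested on simulated data with the lungs' group sizes and independent genes. For dust against saline, with 711 genes run, it recovered 43.3% of 67 genes changed 1.41-fold, 76.1% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 6 false calls among 511 unchanged genes. For Fat-1 against WT in dust the shares were 29.9%, 68.7% and 87.9%, with 6 false calls among 511. With no gene changed, both contrasts called 0 of 711 genes.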

Results

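RNA of 754 genes was measured in the left lungs of 23 mice to compare repeated instillation of organic dust extract with saline in WT mice and in Fat-1 mice, which make omega-3 from omega-6 fatty acids. By extract code there were 4 WT female, 3 WT male, 3 Fat-1 female and 3 Fat-1 male dust lungs, and 2 WT female, 3 WT male, 2 Fat-1 female and 3 Fat-1 male saline lungs. Values are normalized counts with a floor of 20, from 110453 to 812429 recovered counts per lung, and p-values are limma's with Benjamini-Hochberg adjustment over 711 genes.

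The first comparison asked which genes differed between dust and saline lungs over both genotypes and sexes. The largest rises were in chemokines that draw neutrophils and in genes of activated myeloid cells. Cxcl3, a CXC chemokine, rose from 46.3 ± 35.2 normalized counts in saline (SD, n = 10) to 789.6 ± 453 in dust (n = 13), a log2 fold change of 4.11 (SE 0.44, adjusted p = 5.13e-06; 2.89 with a common floor in every lung). Il1rn, the interleukin 1 receptor antagonist, rose from 172 ± 63.2 to 2855 ± 1745, and Mmp12, macrophage elastase, rose from 224 ± 219 to 2075 ± 1347. Ccl9, a chemokine for myeloid cells, rose from 426 ± 188 to 3837 ± 1906 (log2 fold change 3.07, adjusted p = 5.13e-06). Cxcl3, Il1rn and Ccl9 were higher in all 13 dust lungs than in the highest saline lung. Il4i1, an amino acid oxidase of myeloid cells, Clec5a, a myeloid lectin receptor, and Acod1, which makes itaconate, rose by 3.39, 3.03 and 2.98 on the log2 scale. In saline 7 of 10 lungs were at the floor for Il4i1 and 9 of 10 for Acod1, and with a common floor in every lung these genes were at 1.87 and 1.21. Il1b rose from 129 ± 58.1 to 1234 ± 1091, Ccl3 from 97.9 ± 41.8 to 1049 ± 853, and Cxcl2 from 41.0 ± 25.5 to 285 ± 162 (2.68, or 1.58 with a common floor). Csf3r, the receptor for granulocyte colony-stimulating factor, rose from 106 ± 32.6 to 926 ± 756, and Cxcr2, the receptor for these CXC chemokines, from 52.6 ± 33.9 to 463 ± 354.

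The genes that fell most included several of vessels and of growth factor signalling. Angpt1, the ligand of the endothelial receptor Tek, fell by 1.21 on the log2 scale (SE 0.22, adjusted p = 3.05e-04), from 389 ± 78.6 to 179.8 ± 70.4, and all 13 dust lungs were below the lowest saline lung. Tek itself fell from 2061 ± 314 to 1116 ± 342, and Thbd, the endothelial anticoagulant thrombomodulin, fell from 4711 ± 438 to 2482 ± 1043. Bmp6, a bone morphogenetic protein, fell from 1022 ± 126 to 499.8 ± 166, with 12 of 13 dust lungs below the lowest saline lung. Hpgd, which inactivates prostaglandins, fell from 11058 ± 2336 to 5739 ± 2341. Gsn, the actin-severing protein gelsolin, fell from 17748 ± 2698 to 9337 ± 4437, and Tgfbr3, a co-receptor for transforming growth factor beta, from 775 ± 81.2 to 410.2 ± 145. Tspan7, Rasgrf2 and Cdh13 fell by 1.03, 0.98 and 0.95 on the log2 scale, with Cdh13 at −0.57 under a common floor. Cttnbp2 fell by 1.02 and Col17a1 by 0.94, but with a common floor in every lung these were −0.22 (adjusted p = 0.0559) and −0.07 (adjusted p = 0.0787).

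In limma's test 379 of 711 genes passed, 308 higher and 71 lower in dust, and 161 of them changed at least 2-fold. The median of all genes shifted by 0.26 on the log2 scale, or by 0.12 on the scale of the housekeeping genes, where the calls were 254 higher and 115 lower. After median centring of each lung the median of all genes was −0.26, with 170 genes higher and 301 lower, so the balance of directions depended on the scaling. The 20 housekeeping genes had a median log2 fold change of 0.08, with 3 called higher and 0 lower.

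**Figure D1:**
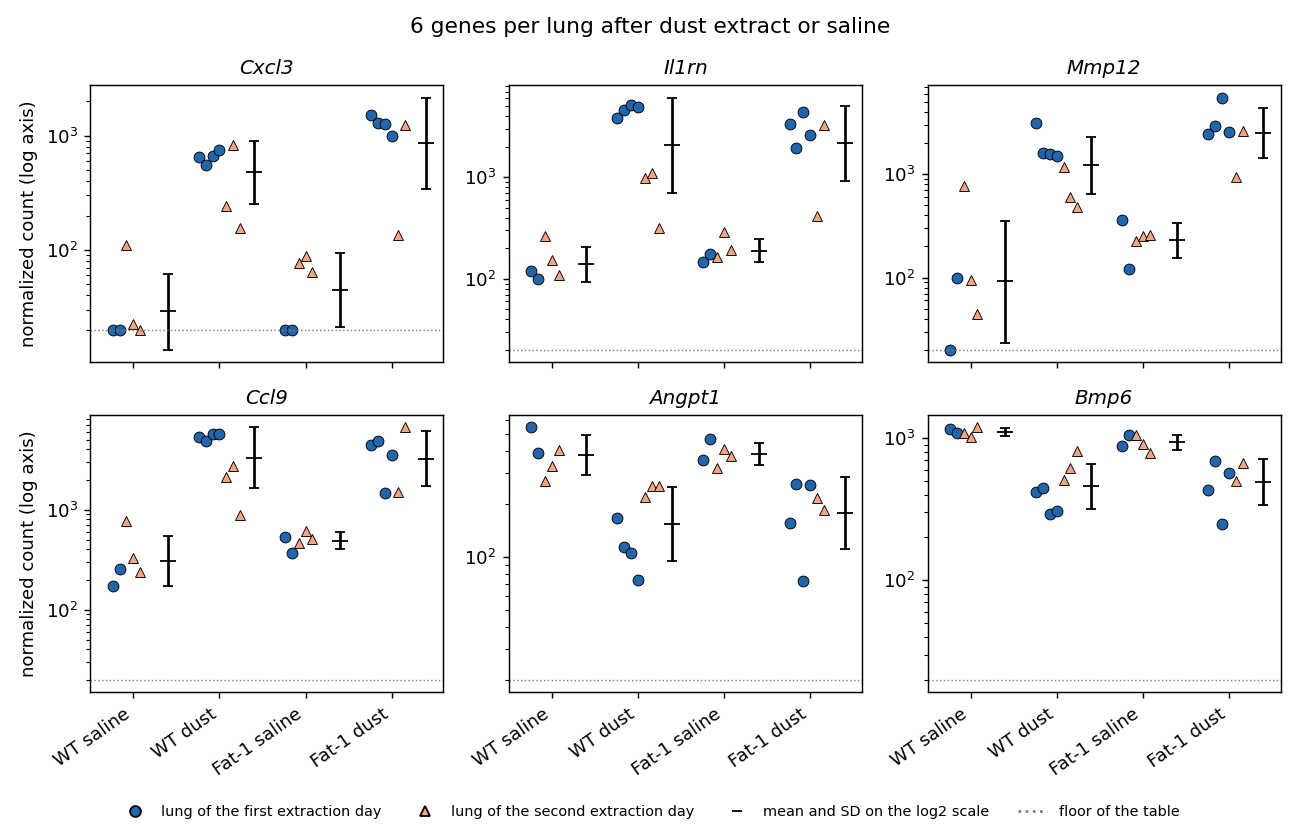
Normalized counts of 6 genes in each lung on a log axis, by genotype and exposure with both sexes pooled, with circles for day 1, triangles for day 2, bars for the mean and SD on the log2 scale and a dotted line at the floor of 20. Cxcl3, Il1rn, Mmp12 and Ccl9 lay higher in dust lungs of both genotypes and Angpt1 and Bmp6 lower. For Cxcl3 the log2 fold change was 2.71 on day 2 against 5.43 on day 1. With a common floor these were 2.15 and 3.40, since all 4 saline lungs of day 1 were at the floor. The day 2 dust lungs were not alike for Cxcl3. Fat-1 male lung 1 was at 1233 and WT male lung 1 at 823, within the day 1 dust lungs (550 to 1529), and the female lungs were at 135 to 243.

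Within the days, 331 genes passed among the 12 lungs of day 1, of which 303 were among the 379. Only Ccl20 passed among the 11 lungs of day 2 (log2 fold change 1.495, adjusted p = 0.0332), with 265 genes at an unadjusted p under 0.05, 3 residual degrees of freedom and 1 lung in each of 5 of the 8 groups. The first cartridge alone gave 164 genes and the second 28. Log2 fold changes on day 1 and day 2 were 4.79 and 2.32 for Il1rn, 4.62 and 2.15 for Mmp12, 3.78 and 2.34 for Ccl9, and 4.49 and 0.96 for Cxcr2. With a common floor they were 4.11 and 2.04 for Mmp12 and 2.70 and 1.02 for Cxcr2. For the falling genes they were −1.68 and −0.60 for Angpt1, and −1.36 and −0.76 for Bmp6. WT female dust lung 2 of day 2 lay within the range of the saline lungs on the saline-to-dust axis over 470 genes (0.156, saline −0.171 to 0.231). The saline lung at 0.231 was WT female lung 1 of day 2, in doubt on technical measures, and the next was at 0.147.

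Of the 15 tested neutrophil-attracting chemokines and cytokines, 14 rose and 0 fell, with a median log2 fold change of 1.94 (2.56 on day 1, 1.06 on day 2, and 1.43 after median centring with 12 higher and 1 lower; camera adjusted p = 0.00207, and adjusted p = 0.607 with an estimated correlation). Besides Cxcl3 and Ccl3 they included Ccl20, a chemokine for lymphocytes and dendritic cells, at 86.5 ± 52.4 in dust against 21.0 ± 2.42 in saline, where 8 of 10 lungs were at the floor. Cxcl5, an epithelial CXC chemokine, was at 126 ± 95.5 against 27.7 ± 9.56. With a common floor their log2 fold changes of 1.83 and 1.94 were 0.29 (adjusted p = 0.0394) and 0.58 (adjusted p = 0.0206). Among 17 neutrophil genes 11 rose and 0 fell, with a median of 1.32, and the list itself missed the threshold (camera adjusted p = 0.0529; 0.0258 after median centring, with 10 higher and 4 lower). The formyl peptide receptors Fpr2 and Fpr1 rose by 2.47 and 1.08 on the log2 scale, from 238 ± 34.6 to 1484 ± 897 and from 143 ± 25.8 to 308 ± 78.5. Fcgr3, an immunoglobulin G receptor, rose by 1.85 and Il1r2, the decoy receptor for interleukin 1, by 1.90. With a common floor these were at 1.78 and 0.49 (adjusted p = 0.0463 for Il1r2).

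Macrophage genes rose as groups. Of 14 alveolar macrophage genes 11 rose and 0 fell (median 0.98; day 1 1.23, day 2 0.97, and 0.46 after median centring with 8 higher and 0 lower; camera adjusted p = 0.00545). Of 18 genes of monocytes and interstitial macrophages 14 rose and 0 fell (median 1.30; day 1 1.56, day 2 0.91, and 0.79 after median centring with 13 higher and 2 lower; camera adjusted p = 0.00505). The adjusted p was 0.607 with an estimated correlation for both lists. Marco, a scavenger receptor, rose from 177 ± 75.0 to 604 ± 274, Itgax, the integrin CD11c, from 105 ± 34.5 to 394 ± 173. The lysosomal protease Ctsd rose from 6287 ± 976 to 16640.2 ± 5271, Cd68 from 549 ± 127 to 1951 ± 804, and Adgre1, which encodes F4/80, from 381 ± 76.0 to 1552 ± 719. Among 9 complement genes 8 rose and 0 fell (median 1.86; day 1 2.25, day 2 1.46, and 1.34 after median centring with 8 higher and 0 lower; camera adjusted p = 0.00207, and adjusted p = 0.607 with an estimated correlation), among them C1qa, C1qb and C1qc, the subunits of C1q, by 1.79, 2.20 and 1.94.

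Inflammatory activation genes and pattern receptors also rose. Of 28 classical activation genes 22 rose and 0 fell (median 1.20; day 1 1.55, day 2 0.74, and 0.68 after median centring with 17 higher and 2 lower; camera adjusted p = 0.00342). Of 20 toll-like and other pattern receptor genes 15 rose and 1 fell (median 0.97; day 1 1.34, day 2 0.71, and 0.45 after median centring with 10 higher and 4 lower; camera adjusted p = 0.0234). The adjusted p was 0.607 with an estimated correlation for both. Tnfaip3, a brake on NF-kappa-B signalling, rose from 246 ± 33.0 to 771 ± 405, the transcription factor Irf5 from 174 ± 26.6 to 425 ± 169.6. Tlr2, a receptor for bacterial lipoproteins, rose from 157 ± 34.0 to 564 ± 177, and Clec7a, the beta-glucan receptor dectin, from 472 ± 110.4 to 2122 ± 1300. Tlr9 and Tlr13, receptors for microbial nucleic acids, rose by 1.55 and 1.73 on the log2 scale, and Tlr5, the flagellin receptor, fell by 0.54. With a common floor Tlr9 was at 0.72 and Tlr5 at −0.04 (adjusted p = 0.508). Of 7 interferon-stimulated genes 4 rose and 0 fell (median 0.56, camera adjusted p = 0.377). Cxcl10 rose by 2.39 (3.90 on day 1, 0.71 on day 2; with a common floor 1.33, 1.87 and 0.53), Isg15 by 1.20 (1.75 on day 1, 0.48 on day 2) and Irf7 by 0.96 (1.39 and 0.36). After median centring Isg15 was at 0.68 (adjusted p = 0.0732) and Irf7 at 0.45 (adjusted p = 0.110), and 1 of the 7 genes was called.

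Endothelial genes were the list that fell. Of 11 tested, 6 fell and 2 rose (median −0.46; day 1 −0.56, day 2 −0.27; camera adjusted p = 0.00342, and adjusted p = 0.212 with an estimated correlation). With Angpt1, Tek and Thbd, the junction cadherin Cdh5 fell from 1572 ± 196 to 1069.6 ± 200.4 and Angpt2 from 231 ± 48.0 to 159 ± 30.3. Selp and Vcam1, adhesion molecules of activated endothelium, rose by 1.00 (0.55 with a common floor) and 0.44 on the log2 scale. After median centring 8 of the 11 were lower and 0 higher, with Selp at 0.48 (adjusted p = 0.107) and Vcam1 at −0.08 (adjusted p = 0.545). Of 16 fibroblast and matrix genes 8 rose and 2 fell (Col17a1 and the protease inhibitor Timp3, which fell by 0.58), but after median centring 3 were higher and 6 lower. Their median was 0.27, with a camera adjusted p of 0.785 in the downward direction, opposite in sign to the median and the mean of 0.36. Tnc, a matrix protein of injured tissue, rose from 222 ± 50.9 to 817 ± 449, Col3a1 from 1872 ± 552 to 5168 ± 2103, Fn1 from 3608 ± 962 to 8248 ± 2371, and Tgfb1 by 0.74 (0.22 after median centring, adjusted p = 0.0700).

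**Figure D2:**
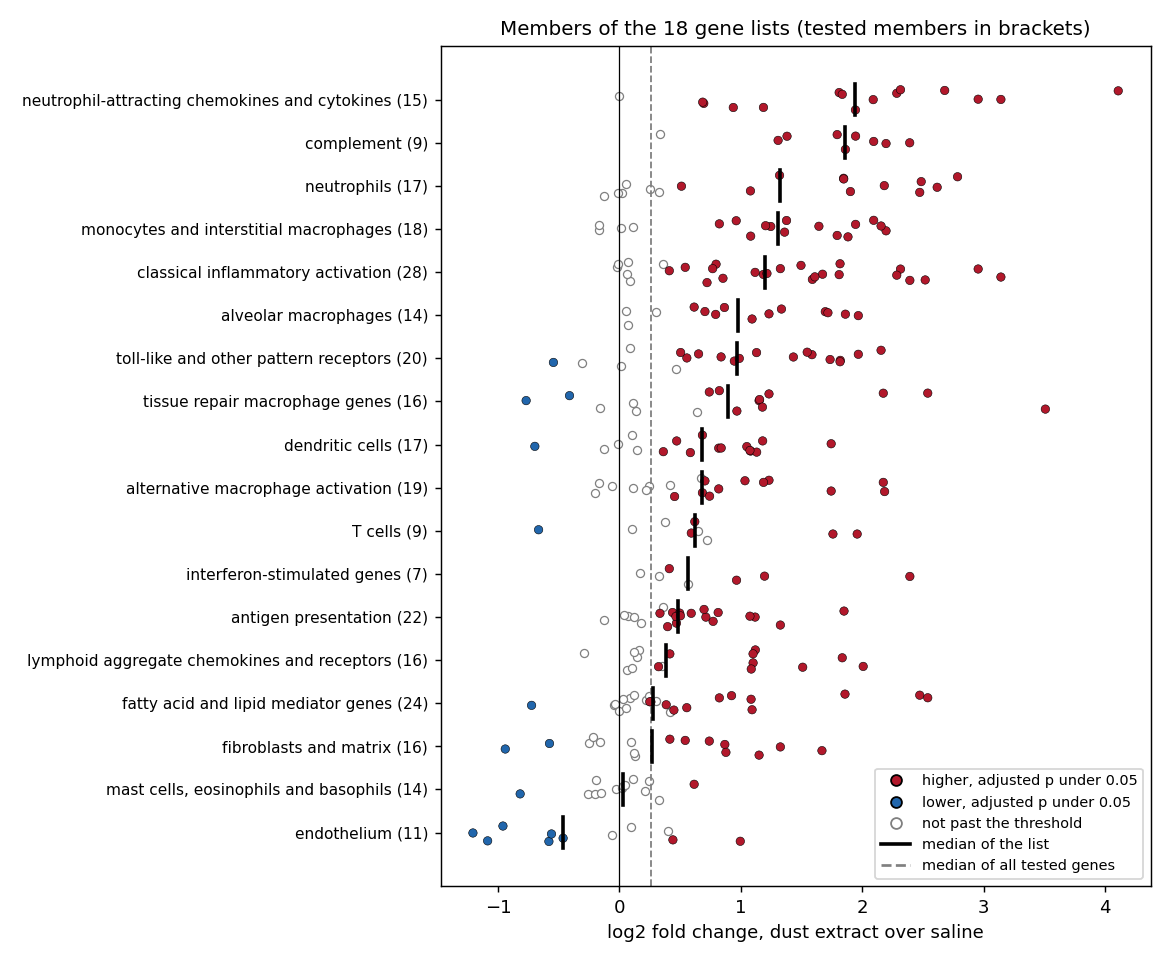
Log2 fold change of each tested member of 18 gene lists in dust against saline, with red points for genes higher at an adjusted p under 0.05, blue for lower and white for neither, a bar at the list median and a dashed line at the median of all genes (0.26). Medians ran from −0.46 in endothelium to 1.94 in neutrophil-attracting chemokines and cytokines, and after median centring those of fibroblasts and matrix, lymphoid aggregate genes, antigen presentation, fatty acid and lipid mediator genes, and mast cells, eosinophils and basophils were below 0.

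The other lists missed camera's threshold but held called members. Of 19 alternative activation genes 11 rose and 0 fell (median 0.68, 0.17 after median centring with 6 higher and 2 lower; camera adjusted p = 0.1999). Ccl8 rose from 65.1 ± 29.8 to 305 ± 190.2, and the chitinase-like Chil3 from 8447 ± 3931 to 21363 ± 8750.4 and Chil4 from 2829.9 ± 1288 to 6684 ± 2341. The interleukin 4 receptor Il4ra rose by 1.03. Of 16 tissue repair genes 10 rose, with Mmp12, Fn1 and Trem2, and 2 fell, Vegfa by 0.77 and Pdgfb by 0.41 (median 0.90, 0.38 after median centring with 7 higher and 4 lower; adjusted p = 0.1999). Igf1 rose by 1.15, but with a common floor in every lung its difference was 0 by construction, since every lung was under that floor. Of 24 fatty acid and lipid mediator genes 12 rose and 1, the fatty acid carrier Cd36, fell by 0.72 (median 0.28, −0.24 after median centring with 5 higher and 6 lower; adjusted p = 0.274). Trem2, a lipid-sensing receptor, rose from 61.5 ± 31.7 to 394 ± 324, Olr1, a receptor for oxidised lipoprotein, from 220.1 ± 50.3 to 854 ± 350.2, and Alox5ap, needed for leukotriene synthesis, from 414 ± 73.0 to 896 ± 265. Of 22 antigen presentation genes 16 rose and 0 fell (median 0.48, −0.03 after median centring with 4 higher and 5 lower; adjusted p = 0.0529). The protease Ctss rose from 1578 ± 308 to 6201 ± 2799 and the co-stimulators Cd86 and Cd80 by 1.33 (0.76 with a common floor) and 1.12.

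Of 17 dendritic cell genes 12 rose and 1, Dpp4, fell by 0.70 (median 0.68, 0.17 after median centring with 5 higher and 4 lower; camera adjusted p = 0.1999). Sirpa rose by 1.18, Fscn1 by 1.13 and Cd1d1 by 1.07, and Flt3 rose by 1.08 but was at 0.01 with a common floor (adjusted p = 0.418). Of 16 lymphoid aggregate genes 9 rose and 0 fell (median 0.38, −0.13 after median centring with 6 higher and 5 lower; adjusted p = 0.210). They included Cxcl13, the chemokine that draws B cells into follicles, from 95.8 ± 29.3 to 414 ± 241, Ccl19 from 66.0 ± 28.8 to 193 ± 104 and Il21r by 1.09. With a common floor Ccl19 was at 0.97 and Il21r at 0.52. Of 9 T cell genes 4 rose and 1 fell (median 0.62, 0.10 after median centring with 2 higher and 2 lower; adjusted p = 0.585). The checkpoint receptor Ctla4 rose by 1.96 (0.59 with a common floor, adjusted p = 0.0276), Icos by 1.76 (0.49 with a common floor, adjusted p = 0.0638) and Cd28 by 0.59 (0.02 with a common floor, 0.08 after median centring). The transcription factor Gata3 fell by 0.67, from 106 ± 20.5 to 68.4 ± 19.3 (−0.28 with a common floor, adjusted p = 0.0154). Of 14 genes of mast cells, eosinophils and basophils, Siglecf rose by 0.62 (0.10 after median centring, adjusted p = 0.623) and Gata2 fell by 0.82, while Kit was at −0.26 (adjusted p = 0.123) and Hdc at 0.33 (adjusted p = 0.178). The median of that list was 0.03, its mean −0.002 and camera's direction downward (adjusted p = 0.135), and its median was −0.11 on the housekeeping scale and −0.49 after median centring, with 0 higher and 9 lower.

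In lists with fewer than 5 tested members, the B cell genes Btk and Fcer2a rose by 0.97 and 1.29 (Fcer2a at 0.04 with a common floor, adjusted p = 0.384), while Ms4a1 was at −0.01 and Cxcr5 at −0.29. The plasma cell gene Irf4 rose by 0.82 (0.05 with a common floor, adjusted p = 0.508; 0.30 after median centring, adjusted p = 0.188), and the epithelial genes were at 0.29 for Lamp3 (adjusted p = 0.0378; −0.23 after median centring, adjusted p = 0.211) and −0.00 for Cdh1. Among cytotoxic cell genes Ccl5 rose by 0.77 (0.25 after median centring, adjusted p = 0.342) and Gzma, a granzyme, fell by 0.82, while Klrk1 was at −0.03 and Nkg7 at −0.13. Counts adjusted over the list alone were those over all genes except for T cells (6 higher, 1 lower), mast cells, eosinophils and basophils (1 higher, 0 lower), pattern receptors (16 higher, 1 lower) and tissue repair genes (11 higher, 2 lower). Of the 18 lists, 7 passed camera at the preset correlation, 0 at an estimated correlation (lowest adjusted p = 0.212), and 17 passed fry.

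The dust response was then measured in each genotype. In WT lungs (dust n = 7, saline n = 5) Cxcl3 rose from 38.5 ± 40.0 to 547.8 ± 253, a log2 fold change of 3.95 (limma adjusted p = 5.70e-04), Ccl9 from 354 ± 241 to 3909.7 ± 1966 and Mmp12 from 205 ± 316 to 1428 ± 861. Il1rn and Clec5a rose by 3.88 and 3.32. Angpt1, Bmp6, Hpgd, Cdh13 and Thbd fell by 1.33, 1.28, 1.25, 1.10 and 1.04 on the log2 scale. In Fat-1 lungs (dust n = 6, saline n = 5) Cxcl3 rose from 54.0 ± 32.3 to 1072 ± 489, a log2 fold change of 4.27 (limma adjusted p = 5.63e-04), and Mmp12 from 242 ± 84.3 to 2830.2 ± 1483. Il1rn, Il4i1 and Ccl3 rose by 3.56, 3.46 and 3.28, and Gsn, Tspan7, Rasgrf2, Thbd and Tgfbr3 fell by 1.45, 1.31, 1.19, 1.14 and 1.11. Part of these falls rests on Fat-1 female dust lung 2 of day 1, a lung in doubt and the lowest Fat-1 dust lung for each. It was at 868 for Gsn, against 7300 to 12130 in the other Fat-1 dust lungs, and at 199 for Tspan7, against 2061 to 2774. The class II genes H2-Ab1 and Cd74 rose by 0.98 and 1.18 in Fat-1 lungs, and complement C3 by 1.68. The rises were 0.80, 0.89 and 1.48 without Fat-1 female dust lung 2 of day 1. In WT lungs they were at 0.45 (adjusted p = 0.134), 0.45 (adjusted p = 0.237) and 1.08 (adjusted p = 0.00880). The difference of these responses between the genotypes did not pass by limma (adjusted p = 0.999 for each).

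**Figure D3:**
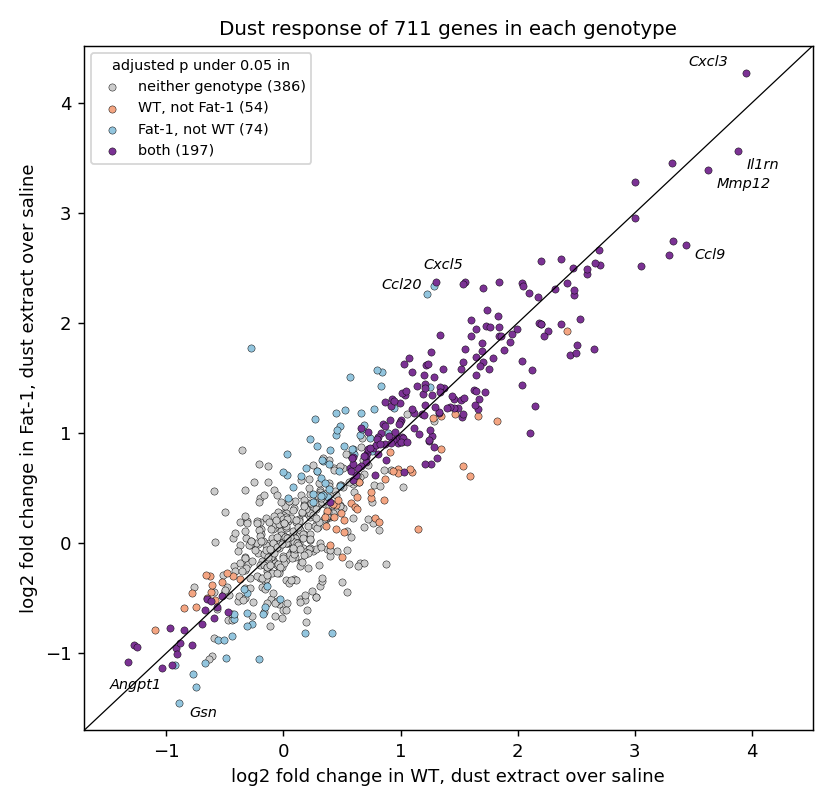
Log2 fold change in dust against saline of 711 genes in WT lungs (horizontal axis) and Fat-1 lungs (vertical axis), with the diagonal of equal change and colours for the genotypes in which each gene had an adjusted p under 0.05. Both genotypes called 197 genes, WT not Fat-1 54 and Fat-1 not WT 74, and no gene differed between the genotypes in its dust response by limma's test of the difference.

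In WT lungs 251 genes passed, 218 higher and 33 lower (120 and 206 after median centring), and in Fat-1 lungs 271, 229 higher and 42 lower (129 and 210 after median centring). The genotypes shared no lungs, and 178 higher genes were common to both against 70.2 for independent lists, with 19 lower genes against 1.95. The model gave each gene the same spread in both genotypes, so genes of small spread were called more readily in both. The overlap is therefore not a test against independent lists. Across genes, which are not independent replicates, the fold changes had a Pearson's r of 0.907 and a Spearman's rho of 0.859. Lists past camera's threshold in WT were complement, alveolar macrophages, monocytes and interstitial macrophages, neutrophil-attracting chemokines and cytokines, pattern receptors, classical activation and neutrophils upward. Downward they were endothelium and mast cells, eosinophils and basophils (for all 9, adjusted p from 0.00321 to 0.0319, and adjusted p = 0.127 to 0.629 with an estimated correlation). In Fat-1 they were neutrophil-attracting chemokines and cytokines, complement, classical activation, monocytes and interstitial macrophages, alveolar macrophages and antigen presentation upward and endothelium downward (adjusted p from 4.42e-04 to 0.0306, and adjusted p = 0.471 to 0.599 with an estimated correlation). Day 1 alone called 253 genes in WT and 203 in Fat-1, and day 2 alone called 1 and 6. In day 2 alone 5 of the 8 groups held 1 lung, and all of these calls but Ccl20 were genes above the floor in 1 or 2 lungs and without spread within groups, so they rest on single lungs and are not counted as results. The cartridges alone called 11 and 0 in WT and 17 and 1 in Fat-1, and that 1 gene was of the same kind. The WT count was 117 without WT female saline lung 1 of day 1 and 139 without the 4 lungs with differing labels. The Fat-1 count was 164 without Fat-1 female saline lung 1 of day 2, 172 without lung 1 of day 1 of that group, 122 without the 4 lungs in doubt and 69 without the 4 with differing labels. Leaving out a female saline lung left the other as the whole of its group.

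Fat-1 and WT lungs were next compared after dust. Ccl20 was at 118 ± 56.1 in Fat-1 (n = 6) and 59.3 ± 31.6 in WT (n = 7), a log2 difference of 0.93 (SE 0.26), which did not pass over all genes (limma adjusted p = 0.979). Maff, a small transcription factor, was at 203 ± 57.4 and 136 ± 26.1 (0.51), and Prok2, prokineticin, was at 35.4 ± 17.8 in Fat-1, with 3 of 6 lungs at the floor and all 7 WT lungs there. The neutrophil-attracting list had a median difference of 0.63 toward Fat-1, with Cxcl5 at 1.00 (184 ± 115 and 76.4 ± 30.9), Il6 at 0.68 and Csf2 at 0.60. Over all genes 0 of its members passed, and adjusted over the list alone 1 did, Ccl20. The list passed camera (adjusted p = 1.42e-04), but its adjusted p = 0.903 with an estimated correlation and 0.958 in fry. No other of the 18 lists passed.

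By limma 0 of 711 genes differed between Fat-1 and WT in dust, with 22 at an unadjusted p under 0.05, and for 581 genes the 95% interval of the difference lay within 2-fold. Day 2 alone called 3 genes and the second cartridge 1, all above the floor in 2 lungs and without spread within groups. Without Fat-1 female dust lung 1 of day 2, 5 genes passed, Ccl17 at 1.96, Cxcl5 at 1.45, Ccl20 at 1.18, Prok2 at 0.87 and Maff at 0.69 (adjusted p from 0.0171 to 0.0233), and without the 4 lungs in doubt the neutrophil-attracting list missed the threshold (adjusted p = 0.0565).

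In saline lungs the genotypes were compared without dust. Clec1b, a platelet lectin receptor, was at 98.3 ± 12.4 in Fat-1 (n = 5) and 72.9 ± 35.2 in WT (n = 5), a log2 difference of 0.78 (0.43 without WT female saline lung 1 of day 1, which was at the floor, and 0.11 with a common floor), and Kitl, the ligand of Kit, at 2956 ± 193 and 2265 ± 504, with Vtcn1 at a difference of 0.43. By limma 0 genes passed, with 10 at an unadjusted p under 0.05 (lowest adjusted p = 1), and 0 lists passed camera. Without the 4 lungs in doubt 15 genes passed, 14 higher in Fat-1, among them Mmp12 at 2.66, Pglyrp1 at 1.93 and Retnla at 1.71, but WT female saline was then a single lung, taken to vary like the other groups. Without WT female saline lung 1 of day 1, Rnase2a at −1.92 and Fbp1 at −0.47 passed, with lung 1 of day 2 as the whole of that group and Fbp1 above the floor in 1 lung.

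The interaction asked whether the dust response differed between genotypes. Rnase2a, an eosinophil-type ribonuclease, was at 82.1 ± 17.4 in Fat-1 dust (n = 6) and 22.7 ± 5.99 in Fat-1 saline (n = 5, 4 at the floor), against 39.9 ± 17.2 in WT dust (n = 7) and 80.2 ± 121 in WT saline (n = 5, 3 at the floor), a log2 difference of responses of 2.05. Ifit1bl1, of an interferon-induced family, was at 60.3 ± 24.7 and 95.9 ± 19.9 in Fat-1 and 112 ± 55.1 and 76.2 ± 8.91 in WT, a difference of −1.23, and Vtcn1 had a difference of −0.64. By limma 0 genes passed, with 21 at an unadjusted p under 0.05 (lowest adjusted p = 0.999), and 347 genes had a 95% interval within 2-fold. No list passed (neutrophil-attracting list adjusted p = 0.173), although that list passed with a common floor (adjusted p = 0.00321), and Rnase2a passed without WT female saline lung 1 of day 1 (3.00, adjusted p = 0.00467). That left lung 1 of day 2, at 295.65, as the whole of its group, and without that lung instead the difference was 1.09 (adjusted p = 0.727). Day 2 alone called 4 genes, each above the floor in 2 lungs and without spread within groups.

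Females and males were compared over both exposures. Tlr8, an X-linked receptor for single-stranded RNA, was at 419 ± 217 in females (n = 11) and 218 ± 93.1 in males (n = 12), a log2 difference of 0.72 that did not pass (adjusted p = 0.826), though it did without WT female dust lung 2 of day 2 (0.82, adjusted p = 0.00362). Smad2, a signal carrier for transforming growth factor beta, was at 123 ± 19.5 and 99.5 ± 15.7, and Fabp4, a fatty acid binding protein, at 185 ± 27.6 and 137 ± 44.4. By limma 0 genes passed, with 17 at an unadjusted p under 0.05, and for 658 genes the 95% interval lay within 2-fold. T cell genes (median 0.26, camera adjusted p = 0.0353), antigen presentation (0.17, 0.0211) and interferon-stimulated genes (0.30, 0.0211) passed camera toward females, with an adjusted p of 1.00 for each with an estimated correlation and in fry. Day 1 alone, with 4 of the 8 groups holding 1 lung, called Col3a1 at 0.85, Il1a at 0.83 and Mmp1a at −0.94, the last above the floor in 3 lungs.

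The last contrast asked whether the dust response differed between the sexes. Retnla, a secreted marker of alternative activation, was at 10556 ± 3836 in dust (n = 7) and 16193 ± 15806 in saline (n = 4) among females, and at 16310.3 ± 10566 (n = 6) and 5873 ± 4272 (n = 6) among males, a log2 difference of responses of −1.91. Chil4 was at 5371 ± 1897 and 3638 ± 1824 in females and 8216 ± 1900.1 and 2291 ± 347 in males, a difference of −1.27, and Lrp6, a Wnt co-receptor, had a difference of 0.61. By limma 0 genes passed, with 14 at an unadjusted p under 0.05 (lowest adjusted p = 0.998). Toward males, camera called alternative activation (median −0.34, adjusted p = 0.00318), neutrophil-attracting (−0.69, 0.00459), alveolar macrophage (−0.26, 0.0297) and mast cell, eosinophil and basophil genes (−0.18, 0.0297), and toward females antigen presentation (0.15, 0.0297) and interferon-stimulated genes (0.48, 0.0297). With an estimated correlation the adjusted p was 0.767 for antigen presentation and 0.688 for the other 5. Retnla passed without WT female saline lung 1 of day 1 (−2.66, adjusted p = 0.0174), which left lung 1 of day 2, at 39489.6, as the whole of its group, and without that lung instead the difference was −1.15 (adjusted p = 1). Day 2 alone called 6 genes with 1 lung in 5 of the 8 groups, and 4 of the 6 were above the floor in 2 lungs and without spread within groups.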

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

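The tests of cartridge, scaling and floor for the difference between days, all tests of the single lung, those of the chemokine list without lungs, and the regroupings for results of 0 genes or 0 lists were chosen after the results were seen, while the estimated correlation was a planned test whose use for the chemokine list was chosen afterwards.

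The difference between days was the first pattern, since on the saline-to-dust axis over the 470 genes above the floor in every lung dust lungs of day 1 lay at 0.788 to 1.589 (n = 8) and those of day 2 at 0.156 to 1.244 (n = 5; exact permutation p = 0.0286, adjusted p = 0.114 over 4 tests). A test of day by exposure found 6 genes, all with a smaller dust response on day 2, but 3 or 4 of the 4 day 1 saline lungs were at the floor for each, and with a common floor 0 genes passed (Cxcl10 −3.21 to −1.43, Cxcl2 −3.02 to −1.31, Nfkbie −2.46 to −0.88), so that for these genes a smaller response cannot be told apart from the floor set before scaling. Without the lungs in doubt the test of day by exposure found 167 genes (112 among genes above the floor in every lung). The difference was thus present among the other lungs too. The rise itself decides nothing, since those left out included the day 2 dust lung at 1.244, the highest of its day. They also included the day 1 dust lung at 1.589. The cartridge as the whole cause is argued against by the day 1 dust lungs on the second cartridge, at 1.33 and 1.448 on the axis. On the housekeeping scale the difference between the days was 0.553 against 0.529, so it was not smaller there. That scale could change little, since the housekeeping geometric mean ran only from 446.7 to 569.4 between lungs. The axis was not placed after median centring, so scaling as a cause stays open. Handling on the extraction day, a separate cohort of mice and a longer time after the last instillation may each account for the day difference. These were addressed only in part, since the days differed in 49 genes in dust and 1 in saline. Saline lungs lay −0.059 apart on the axis (exact permutation p = 0.560, adjusted p = 0.747), a miss that does not show equality. Without WT female dust lung 2 of day 2 the axis difference was 0.445 (exact permutation p = 0.0578, adjusted p = 0.116), with 4 genes by exposure, and between the days in dust 6 genes in place of 49 were called and 163 in place of 225 had an unadjusted p under 0.05.

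WT female dust lung 2 of day 2 was the second pattern, as a lung far from the others of its group. Il13 was at 51.2 there with the others at the floor, where the gap over range is 1 for any value above it. For Ctsd, Trem2 and H2-Ab1 this lung was at 8045, 106 and 4358. The other 3 lungs were at 21601 to 23928, 448 to 497 and 8089 to 8633 (gap over range 0.853, 0.874 and 0.873 for this lung). The place of this lung on the axis, 0.156, was inside the range of the saline lungs, as for a saline lung carrying a dust label. That range ended at 0.231 in WT female saline lung 1 of day 2, a lung in doubt on technical measures. The next saline lung was at 0.147, so 0.156 was inside the range only through that lung in doubt. WT female dust lung 2 of day 2 lay −1.8 SD from the mean of the other day 2 dust lungs. With only 4 other lungs, a small day 2 response cannot be told apart from a saline lung. Against a saline lung, this lung lay above all 10 saline lungs for 18 of 78 named genes that rose. Among them were Cxcl3 (157 against at most 110.1), Il1rn (316 against 289), Ccl9 (890 against 773) and Marco (515 against 339). This lung lay below all of them for Angpt1 and Gata3. But over 318 genes called higher without it, it exceeded 9 saline lungs in 15.3% (mean over the 10 sets of 9), against 1.03% to 27.3% for each saline lung treated alike, so that both explanations stay open. A failed hybridisation is argued against, since 0 of 6 technical measures were outside the range of the other lungs.

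The neutrophil-attracting list, higher in Fat-1 than in WT dust lungs, was the third pattern. Without the 4 lungs in doubt on technical measures its camera adjusted p was 0.0565, and its median difference went from 0.63 (members −0.16 to 1.00, median SE 0.49) to 0.27 (−0.46 to 0.91, median SE 0.50). Without only the 2 dust lungs among them the call stayed (0.0289, median 0.27), while of the 8 other pairs of a Fat-1 female and a Fat-1 male dust lung the 3 with female lung 1 of day 1 ended it (0.0671 to 0.131) and the 3 with female lung 1 of day 2 gave medians of 1.07 to 1.12, so the lungs in doubt cannot be told apart from other single lungs as its source. With an estimated correlation between the list's genes the adjusted p was 0.903, so shared variation of the genes could not be set aside. An effect of the Fat-1 transgene on these chemokines stays open, and 0 genes passed alone.

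Among 119 tests of named genes in the group of 4 lungs, 6 had a lung far from the rest. Chance gives about 1 in 20, which is near that share, so these flags alone do not set a lung apart. The other 2 were in WT female dust lung 2 of day 1, with Gata3 at 37.0 against 78.6 to 81.6 (gap over range 0.933) and H2-Ob at 489 against 216 to 254 (0.861). The dust response differed between the sexes by camera in alveolar macrophage, mast cell, eosinophil and basophil, antigen presentation and interferon-stimulated genes (adjusted p = 0.0297 each), in neutrophil-attracting genes (0.00459) and in alternative activation genes (0.00318), and in none of these with an estimated correlation (0.688 to 0.767).

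Other splits of the lungs within strata, 100 for each result with the real split included, were also fitted. Chance was unlikely for dust against saline, where the real split called 379 genes and the highest other 7 (1 split as large). It was also unlikely for WT, with 251 against 185 (1), and for Fat-1, with 271 against 334 (2). These ranks among 100 splits were not adjusted over the results, and the splits did not keep to the days. The Fat-1 split that called more set the 5 saline lungs and Fat-1 female dust lung 1 of day 2 against the other 5 dust lungs. The WT split with 185 likewise set the 5 saline lungs and 2 dust lungs against the other 5 dust lungs. Chance could not be excluded for the 7 lists in dust against saline, with 9 in the highest other split and 7 splits as large, nor for the 1 list in Fat-1 against WT dust, with 10 in the highest other and 77 splits as large. For results of 0 all 100 splits were as large by construction, which decides nothing, and the highest others were 277 genes for Fat-1 against WT in dust, 1 in saline, 12 for genotype by exposure, 160 for female against male, 103 for sex by exposure and 8 lists for genotype by exposure. The split with 277 genes partly followed the day, with 5 of 6 lungs from day 1 on a side against 3 of 7, and its sides lay at mean places of 1.371 and 0.662 on the saline-to-dust axis. The split with 160 genes had sides at 0.861 and 0.288. Such counts point to a structure among the lungs that the groups do not hold. Within day 1 and day 2 the real contrast of the genotypes in dust called 0 and 3 genes.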

How the results depend on the processing

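Cartridge, common floor, housekeeping scale, lungs in doubt and day by exposure were settings chosen after the data were seen. The number of genes in dust against saline stayed within 1.5 times of 379 except with day 2 alone (1), the first cartridge alone (164) and the second (28), where fewer lungs were fitted. Of the 379, 303 were called with day 1 alone, 274 with the 4 lungs of differing labels left out and 330 with a common floor, where 16 more were at 0 because every lung was under that floor. Median centring called 471 genes, of which 241 were among the 379 with the same sign, and 56 of the 379 took the opposite sign (3 of them past the threshold). With day 2 alone 1 of the 379 had the opposite sign. In WT (251) the count was 139 without the lungs of differing labels, 1 with day 2 alone, and 11 and 0 with the first and second cartridge. In Fat-1 (271) it was 69 without the lungs of differing labels, 167 with groups from the characteristics, 6 with day 2 alone, 17 and 1 with each cartridge, and 122 without the lungs in doubt. With the replicate number within day as a block the Fat-1 count was 160, the count for dust against saline was 277, that in WT 187, and the contrasts with 0 genes stayed at 0. By median correlation, same-numbered lungs of a day were no more alike than others, with −0.03 over 65 pairs (lowest −0.41) against 0.01 over 165 other pairs. Of 23 lungs, 10 correlated best with their own number. That count was not set against the share expected by chance, so a pairing of the lungs is not excluded.

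Contrasts with 0 genes gave a few elsewhere. Fat-1 against WT in dust gave 3 with day 2 alone and 1 with the second cartridge. The same contrast in saline gave 1 with day 2 alone, 1 with a common floor and 15 without the lungs in doubt. Genotype by exposure gave 4 with day 2 alone, 1 with the second cartridge and 1 with a common floor. Female against male gave 3 with day 1 alone and 1 with a common floor. Sex by exposure gave 6 with day 2 alone, 1 with the second cartridge, 1 with a common floor and 3 without the lungs in doubt. The gene at the common floor was Coasy each time, with differences of at most 0.07 in size on the log2 scale. In day 2 alone and in the second cartridge alone 5 of the 8 groups held 1 lung, and in day 1 alone 4. Most calls there in contrasts with 0 genes were genes above the floor in 2 lungs and without spread within groups. Without the lungs in doubt 1 group held 1 lung, as when a female saline lung was left out, and such a lung was taken to vary like the other groups. The cause was not tested for the other changes.

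Of the lists, 7 passed in dust against saline, 0 with an estimated correlation and 17 in fry, which does not compare a list with other genes. The 1 list of Fat-1 against WT in dust became 0 with an estimated correlation, 0 in fry, 3 without the lungs of differing labels, 2 with groups from the characteristics, 4 with median centring and 2 with the cartridge as a covariate. The 0 lists of genotype by exposure became 1 without the lungs of differing labels, 1 with groups from the characteristics and 1 with a common floor. Leaving out each lung in turn gave 336 to 402 genes for dust against saline, 117 to 307 in WT, 164 to 336 in Fat-1, 0 to 5 for Fat-1 against WT in dust, 0 to 2 in saline, 0 to 1 for genotype by exposure, female against male and sex by exposure, 7 to 9 lists in dust, 0 to 3 for the lists of Fat-1 against WT in dust and 0 to 3 for those of genotype by exposure. Among values of genes that the naming rule took, each in the contrast that named it, 7803 kept direction and side of the threshold, 535 lost the call and 16 gained it. A further 23, of genes not called in the main fit, took the opposite sign. Called genes outside these counts could change sign too, as Lamp3 and Vcam1 did after median centring in dust against saline. Depth limits the low genes, since 241 tested genes were at the floor in at least 1 lung.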

Other observations

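The 5 gene groups here, and their tests, were chosen after the panel's names and some gene values were seen.

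Genes of cell division rose with dust, 8 of 11 tested and 0 lower, with a median log2 fold change of 1.01. Among them were Ccnb2, a mitotic cyclin, at 1.20, Kif20a, a mitotic kinesin, at 1.14, Birc5, survivin, at 1.08 and Top2a, a topoisomerase of dividing cells, at 1.01. Growth factors and receptors of mesenchyme and vessels went the other way, with 13 of 27 lower and 1 higher, Igf1 (median −0.31). Fgf18 fell by 0.88, Vegfa by 0.77, the Wnt receptor Fzd4 by 0.64, Fgf7 by 0.57, Kitl by 0.55 and Hgf by 0.47. Of 8 eosinophil genes, for granule proteins, ribonucleases and surface receptors, 3 rose, Ear6 by 0.63, Siglecf by 0.62 and Ear3 by 0.54. Not called were Rnase2a at 0.75, Rnase2b at 0.48, Prg2 at 0.21, Il5ra at 0.02 and Ccr3 at −0.03. Of 4 formyl peptide receptors Fpr1 and Fpr2 rose, while Fpr-rs4 was at −0.19 and Fpr3 at −0.26 (neither called). Early response genes, most of them transcription factors, split, with 6 higher and 3 lower of 18. The phosphatase Dusp2 was at 1.51, Egr3 at 0.80 and Egr2 at 0.72, and Fosb was at −0.73, Klf4 at −0.62 and Jun at −0.38. With a common floor in every lung Ccnb2 was at 0.57, Dusp2 at 0.56, Kif20a at 0.17 (adjusted p = 0.109), Egr3 at 0.11 (adjusted p = 0.318) and Fosb at −0.18 (adjusted p = 0.0893), and Birc5, Ear6 and Egr2 could not be compared, since every lung was under that floor. After median centring Ccnb2 (0.68), Ear6 (0.11), Siglecf (0.10), Ear3 (0.03), Egr3 (0.29) and Egr2 (0.20) were not called.

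The hypothesis that each group moves on balance in a single direction with dust was tested with fry. The adjusted p was 0.00092 for cell division, 0.0051 for eosinophil genes, 5.8e-06 for formyl peptide receptors and 0.00129 for growth factors and receptors. It was 0.172 for early response genes, for which the hypothesis was not borne out. On the members that the naming rule had not taken, the adjusted p was 0.00449 for eosinophil genes (5) and for growth factors and receptors (20). For cell division these were all 11 tested genes, so its adjusted p of 0.00184 repeats the first test and adds nothing. The formyl peptide receptors had been chosen for Fpr1 and Fpr2, and their other 2 genes went downward (adjusted p = 0.293), so that their p decides nothing on the group. Against the other panel genes with an estimated correlation, the adjusted p was 0.0600 for growth factors and receptors and 0.684 to 0.756 for the others. The medians of the eosinophil and formyl peptide receptor groups were −0.005 and −0.07 after median centring, so their direction relative to the panel stays open. RNA of whole lungs does not separate a change in cells from a change within them, and no cause was tested for any of the groups.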
